A study of Mus musculus with 139 samples.

How the data were processed

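Total RNA of the left lung was measured with dual-colour Agilent whole mouse genome arrays, 1 array per mouse and 139 arrays on 18 slides. Per the labels, 200 ng of lung RNA was labelled with Cy5 and hybridised against a universal mouse reference RNA, pooled from 11 cell lines, labelled with Cy3. Per the labels, the mice were female C57BL/6, the vehicle was water with 2% serum, and lungs were taken after exsanguination. Replicates are separate animals, as the animal numbers in the labels show. The doses 18, 54 and 162 µg, the day and the material were taken from the labels. The titles of some samples give 164 where the characteristics give 162, which was used. For 3 NM-401 samples titled as repeats, dose and day come from the characteristics alone. Of these, 1 (162 µg, day 1) lay on a slide of day 28 and, with slides as blocks, adds nothing to any comparison.

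Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.3.1 and hold each spot's intensity, as median pixel signals and median local background of both channels. The same deposited files hold the processed intensity that the extraction software corrected for background and dye, which served as an alternative. The deposited value table of the authors holds log2 ratios of lung over reference, normalized within each array by steps that the labels do not state. Its column medians ran from -0.0494 to -0.0155, and its correlation with an own loess fit of uncorrected median signals ran from r = 0.994 to 0.998 across probes. The table served as an alternative to the scanner files.

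The median signals were read with limma 3.58.1 in R 4.3.3, corrected for background with normexp (offset 50), and normalized within each array by loess, with control spots at weight 0. The plan had named mean signals, which the files do not hold, so medians were used. Spots marked as non-uniform by the extraction software were left out, 2443 of all spots on 139 arrays, and 0 spots were saturated. Spots of 1 probe were averaged. A probe was kept if its lung signal was well above background on at least 4 arrays of at least 1 group, which left 32727 of 55681 probes. Probes were matched to symbols through RefSeq accessions, 26413 probes to 20018 symbols, and 29268 probes have no symbol here. Each gene is represented by the probe with the highest mean lung signal, chosen without regard to group. This left 24368 genes and unnamed transcripts, 15110 of them with a symbol. Positions in the genome were not used here, since the array design and the annotation are on different builds.

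All 139 arrays entered 1 limma fit with 24 groups and the slide as a fixed block (99 residual degrees of freedom). Every p in the text comes from this moderated test of limma or, for gene lists, from limma's camera, two-sided, with Benjamini-Hochberg adjustment over the genes of a contrast or the 34 lists of a contrast. The 38 contrasts were each dose against the vehicle group of its material and day, 162 against 18 µg, the response to NM-401 minus the response to NRCWE-26, the response to 162 µg on day 28 minus that on day 1, and NM-401 vehicle against NRCWE-26 vehicle. The reference RNA cancels in each. A gene counts as changed at an adjusted p under 0.05 and a fold of at least 1.5. camera used a preset correlation of 0.01 between genes, and its p is also given with the correlation estimated from the residuals. The 34 lists hold 560 genes, of which 508 were measured, and some genes belong to several lists. The contrasts, lists, thresholds and the rule for named genes were set before the data were examined.

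That rule names, at 162 µg, the 6 largest rises and 4 largest falls among changed genes with a symbol that moved the same way in every slide holding both groups, and up to 4 changed members of each list described. For the difference between materials at 162 µg it names the 3 largest each way, for 18 and 54 µg the 3 largest rises and 2 largest falls, and for 162 against 18 µg and for the vehicle groups the 2 largest each way. The comparison of day 28 with day 1 had no such rule, so the 2 largest each way were named after their values were seen. Not every gene that the rule picks is printed. Where a group's arrays lay near background, a fold is given as a lower bound against the background level of the arrays.

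The fit was tested on simulated data with 200 changed genes added to the design. At a fold of 2 it recovered 95.5%, 97% and 88.1% of the 67 genes changed by that fold for NM-401 162 µg on day 1, NRCWE-26 162 µg on day 3 and the difference between materials at 162 µg on day 28, and at a fold of 1.5 it recovered, again of 67, 47.8%, 37.3% and 29.9%. It called 1, 2 and 1 unchanged genes. The shifted list was found each time, also with an estimated correlation (adjusted p up to 2.32e-11), and 0 of the 33 other lists were. Most real shifts were lost with it, so the simulation does not test false calls where genes move together.

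Alternatives tried were no background correction, the processed intensities, the authors' table, quantile normalization of average intensity between arrays, no or a stricter filter on dim probes, no slide block, slide as a random block, each day fitted alone, 1 value per probe, both vehicle groups pooled, other probes of a named gene, and each array left out in turn where a group held 5 arrays or fewer. Leaving out slides 1 and 9 and the estimated correlation were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.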

Results

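RNA from the left lung of 139 female C57BL/6 mice was measured after a single instillation into the trachea of vehicle or of multi-walled carbon nanotubes. The labels name NRCWE-26 as a short and NM-401 as a long nanotube, and the series compares both at matched doses and times. The doses were 18, 54 and 162 µg per mouse, and lungs were taken on day 1, 3 or 28. Each material had its own vehicle group on each day, which gives 24 groups. A group held 6 mice, except 5 in the NM-401 vehicle and 54 µg groups of day 3, 4 in the NRCWE-26 vehicle group of day 3 and 5 in the NRCWE-26 vehicle group of day 28. Each array carried lung RNA of 1 mouse against a common reference RNA. Of the probes on an array, a median of 53.9% (lowest 30.6%, highest 75.2%) gave a lung signal well above background, and the number of arrays limits the precision. Values below are log2 fold changes ± standard error unless stated otherwise, each p of a gene is adjusted over all 24368 genes and unnamed transcripts tested, and each p of a gene list over the 34 lists of a comparison. A gene is said to have changed, risen or fallen at an adjusted p under 0.05 with a fold of at least 1.5.

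On 2 of the 18 slides, 1 and 9, the response to 162 µg agreed less with the other slides of the same day than on any other slide that holds both arrays. On slide 9 (day 28) the difference between the arrays labelled 162 µg and vehicle ran opposite to the mean of the other day 28 slides, with r = -0.81 for NM-401 and r = -0.74 for NRCWE-26 across genes, which are not independent replicates. The other day 28 slides gave r from 0.483 to 0.821. On slide 1 (day 1) r was 0.219 and 0.146, against 0.377 to 0.815 on the other day 1 slides. Every array is kept under its label, and a further fit of the 123 arrays left without slides 1 and 9, chosen after this was seen, stands beside each fold and each count over all genes that it moves by over 1.5 times and beside each list test that it moves across the threshold. Where any alternative moves a count by over 1.5 times, its range over all alternatives is given too, with 1 array left out among them in groups of 5 arrays or fewer.

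**Figure D1:**
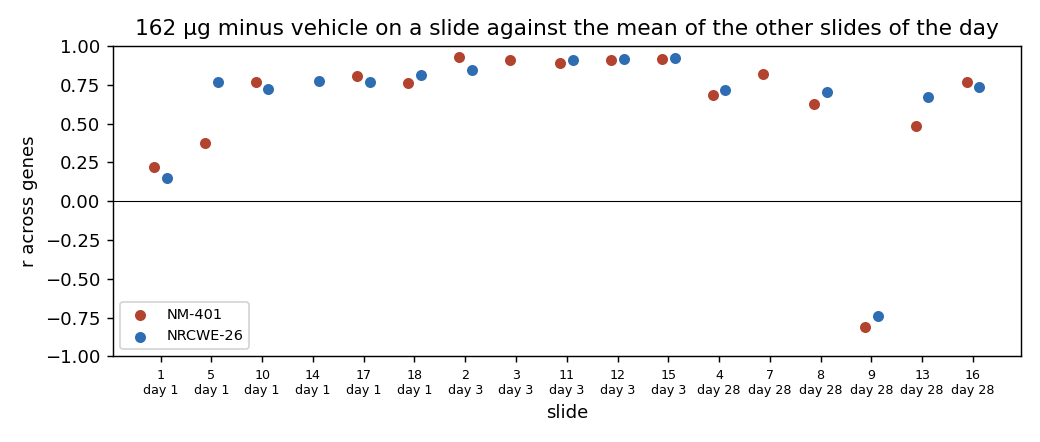
Pearson's r across genes between the difference of 162 µg and vehicle on a slide and the mean of that difference on the other slides of the same day, by slide and material. Slide 9 lies at -0.81 and -0.74, and the slides of day 3 lie between 0.842 and 0.93.

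On day 1 after 162 µg of NM-401, acute phase, neutrophil and glucocorticoid and stress genes were higher in the lung, and NK and B cell markers were lower. With an estimated correlation 0 of 16 list shifts held. Saa3, an acute phase serum amyloid made in the lung, rose by 4.29 ± 1.14, from a log2 ratio of lung to reference of -2.52 ± 1.96 (SD, n = 6) to 1.75 ± 3.08 (SD, n = 6). The metallothionein Mt2 rose by 3.39 ± 0.54 (123 arrays: 4.16 ± 0.39), the retinoic acid producing enzyme Aldh1a3 by 3.36 ± 0.41, the lipase inhibitor Angptl4 by 2.93 ± 0.41, Saa2 by 2.91 ± 0.56 and the decoy interleukin 1 receptor Il1r2 by 2.88 ± 0.40 (123 arrays: 3.50 ± 0.34). Falls were measured for Colq (-2.17 ± 0.43), the granzyme Gzma (-1.90 ± 0.34), Ifi27l2a (-1.66 ± 0.46) and Spon2 (-1.54 ± 0.40). These 10 genes moved the same way in 5 of 5 slides, with adjusted p up to 0.0045.

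Of the acute phase proteins, 16 of 21 rose after 162 µg of NM-401 on day 1. Acute phase proteins had a median of 1.98 and 17 changed when adjusted over the list alone (adjusted p = 1.09e-12, but 0.0586 with an estimated correlation). The neutrophil attracting cytokines rose in 9 of 13 genes, among them Cxcl5 (3.91 ± 0.80), Cxcl1 (2.92 ± 0.54, 123 arrays: 3.58 ± 0.48), Il1b (2.85 ± 0.37) and Il6, which was at least 6.72-fold higher against vehicle arrays near background. The neutrophil attracting cytokines had a median of 0.82 (adjusted p = 5.63e-08, but 0.0586 with an estimated correlation), with 10 changed when adjusted over the list alone. Neutrophil markers rose in 12 of 18, including S100a8 (2.47 ± 0.44), Stfa2l1 (2.48 ± 0.41) and the collagenase Mmp8 (1.83 ± 0.39). Among neutrophil markers the median was 0.99 and 12 changed when adjusted over the list alone, with adjusted p = 5.63e-08, but 0.0586 with an estimated correlation (123 arrays: 0.0422). Of the glucocorticoid and stress genes, lower in these vehicle mice than in those of NRCWE-26 (median -0.55), 9 of 14 rose, such as Fkbp5 (1.83 ± 0.35) and Mt1 (1.81 ± 0.30). For glucocorticoid and stress genes the median was 1.17 (adjusted p = 5.63e-08, but 0.0586 with an estimated correlation, 123 arrays: 0.0422), and 10 changed when adjusted over the list alone. NK cell markers fell in 8 of 10, among them Klra8 (-1.44 ± 0.30) and Klrd1 (-0.95 ± 0.23). NK cell markers had a median of -0.80 and 8 changed when adjusted over the list alone (adjusted p = 1.26e-07, but 0.175 with an estimated correlation). B cell and plasma cell markers fell in 6 of 16, including the complement receptor Cr2 (-1.36 ± 0.25) and Ms4a1, which encodes CD20 (-1.04 ± 0.31). The B cell and plasma cell markers had a median of -0.55 (adjusted p = 6.19e-05, but 0.322 with an estimated correlation), with 6 changed when adjusted over the list alone. Mesothelial cell genes fell in 7 of 11, such as Lrrn4 (-1.40 ± 0.24) and Upk3b (-1.09 ± 0.26). Among mesothelial cell genes the median was -0.72 and 8 changed when adjusted over the list alone, with adjusted p = 0.00822, but 0.322 with an estimated correlation. Of the cardiac muscle genes, lower in these vehicle mice than in those of NRCWE-26 (median -1.78), 3 of 13 rose, with Myh6 at 2.35 ± 0.62. For cardiac muscle genes the median was 1.14 (adjusted p = 0.00476, 123 arrays: 0.0764, but 0.632 with an estimated correlation), and 3 changed when adjusted over the list alone. In all, 1568 (877 higher, 691 lower, range 1447 to 2681) genes and transcripts changed (6 mice against 6, 1 on a day 28 slide adding nothing), and 2497 in the 123-array fit.

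On day 1 after 162 µg of NRCWE-26, acute phase and neutrophil attracting cytokine genes were also higher, and genes of ciliated cells were lower, while 0 of 11 list shifts held with an estimated correlation. The neutrophil chemokine Cxcl5 rose by 3.71 ± 0.75, Mt2 by 3.45 ± 0.51, the fibrinogen chain Fgg by 3.13 ± 0.49, Serpina3m by 2.85 ± 0.39, Il6 by 2.84 ± 0.50 and Akr1c14 by 2.57 ± 0.28. Falls were measured for Colq (-2.48 ± 0.41), the axonemal dynein Dnah6 (-2.24 ± 0.22), Vpreb3 (-2.13 ± 0.21) and 1600029I14Rik (-1.88 ± 0.22, but 0.002 from the extraction software's own processed signals). All 10 moved the same way in 6 of 6 slides (adjusted p up to 3.97e-05). Acute phase proteins rose in 16 of 21. Acute phase proteins had a median of 1.18 and 16 changed when adjusted over the list alone (adjusted p = 2.07e-06, but 0.551 with an estimated correlation). Neutrophil attracting cytokines rose in 7 of 13 and fell in 1. The neutrophil attracting cytokines had a median of 0.66 (adjusted p = 0.00242, but 0.586 with an estimated correlation), with 8 changed when adjusted over the list alone. Ciliated cell genes fell in 12 of 15, among them the dynein Dnah5 (-1.99 ± 0.23), Rsph1 (-1.56 ± 0.16) and Hydin (-1.26 ± 0.20). Among ciliated cell genes the median was -0.88 and 12 changed when adjusted over the list alone, with adjusted p = 2.64e-13, but 0.168 with an estimated correlation. Cell cycle genes fell in 11 of 26 and rose in 1, the cell cycle inhibitor Cdkn1a (2.28 ± 0.25), while Birc5 fell (-1.36 ± 0.30) along with Mki67 (-1.04 ± 0.24). For cell cycle genes the median was -0.50 (adjusted p = 0.00791, but 0.83 with an estimated correlation), and 12 changed when adjusted over the list alone. Cell cycle genes had adjusted p = 0.189 in the 123-array fit, where 4 fell. Glucocorticoid and stress genes rose in 8 of 14, with Fkbp5 at 2.03 ± 0.33. Glucocorticoid and stress genes had a median of 1.04 and 8 changed when adjusted over the list alone (adjusted p = 8.66e-05, but 0.54 with an estimated correlation). NK cell markers fell in 6 of 10, with Gzma at -1.45 ± 0.33. The NK cell markers had a median of -0.65 (adjusted p = 6.85e-04, but 0.586 with an estimated correlation), with 6 changed when adjusted over the list alone. Counting all genes and transcripts, 2254 (995 higher, 1259 lower, range 2176 to 3515) changed (6 mice against 6).

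On day 3 after 162 µg of NM-401, acute phase, chemokine, interferon, cell cycle and matrix genes were higher together, and genes of ciliated and other epithelial cells were lower. Of 16 list shifts 0 held with an estimated correlation. Saa3 rose by 7.66 ± 1.14, from a log2 ratio of -3.15 ± 0.47 (SD, n = 5) to 4.43 ± 0.33 (SD, n = 6). The interferon inducible chemokine Cxcl10 rose by 7.34 ± 0.71, the monocyte chemokines Ccl7 by 6.15 ± 0.68 and Ccl2 by 5.21 ± 0.56, the itaconate producing enzyme Acod1 by 5.92 ± 0.56 and Saa1 by 5.91 ± 0.85. Colq (-3.79 ± 0.43), the fatty acid binding protein Fabp1 (-3.18 ± 0.54), the sodium channel Scn3a (-2.88 ± 0.32) and Pon1 (-2.79 ± 0.34) fell the most. These genes moved the same way in 5 of 5 slides (adjusted p up to 3.57e-07).

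Interferon response genes rose in 20 of 22 on day 3 after 162 µg of NM-401, such as Rsad2 (4.47 ± 0.44), Isg15 (4.26 ± 0.50) and Irf7 (4.05 ± 0.48). Among interferon response genes the median was 2.27 and 20 changed when adjusted over the list alone, with adjusted p = 1.06e-12, but 0.266 with an estimated correlation. Cell cycle genes rose in 25 of 26, with Birc5 at 3.33 ± 0.32, the ribonucleotide reductase subunit Rrm2 at 2.86 ± 0.28 and the proliferation marker Mki67 at 2.39 ± 0.26. For cell cycle genes the median was 1.71 (adjusted p = 1.39e-21, but 0.142 with an estimated correlation), and 25 changed when adjusted over the list alone. Of the extracellular matrix and fibrosis genes 23 of 33 rose, including the protease inhibitor Timp1 (4.94 ± 0.62), Vcan (2.46 ± 0.27) and the collagen Col3a1 (2.31 ± 0.28). Extracellular matrix and fibrosis genes had a median of 1.13 and 25 changed when adjusted over the list alone (adjusted p = 5.82e-09, but 0.142 with an estimated correlation, 123 arrays: 0.023). Acute phase proteins rose in 17 of 21, and monocyte and T cell attracting chemokines in 10 of 16. The acute phase proteins had a median of 1.77 (adjusted p = 3.11e-07, but 0.266 with an estimated correlation), with 17 changed when adjusted over the list alone. Among monocyte and T cell attracting chemokines the median was 2.53 and 11 changed when adjusted over the list alone, with adjusted p = 1.55e-04, but 0.301 with an estimated correlation. Ciliated cell genes fell in 12 of 15, such as Dnah5 (-1.70 ± 0.24) and Rsph1 (-1.26 ± 0.17). For ciliated cell genes the median was -1.03 (adjusted p = 4.12e-07, but 0.266 with an estimated correlation), and 12 changed when adjusted over the list alone. Club cell genes fell in 5 of 9, among them Aldh1a1 (-2.06 ± 0.24) and the secretoglobin Scgb1a1 (-0.96 ± 0.17). Club cell genes had a median of -0.93 and 5 changed when adjusted over the list alone (adjusted p = 0.00356, but 0.301 with an estimated correlation). Alveolar type 1 cell genes fell in 7 of 11, such as Igfbp2 (-1.37 ± 0.24). The alveolar type 1 cell genes had a median of -0.69 (adjusted p = 0.00811, but 0.512 with an estimated correlation), with 8 changed when adjusted over the list alone. B cell and plasma cell markers fell in 9 of 16, while Cxcl13, a chemokine that attracts B cells, rose by 3.80 ± 0.51. Among B cell and plasma cell markers the median was -0.71 and 10 changed when adjusted over the list alone, with adjusted p = 0.00696, but 0.512 with an estimated correlation. The comparison held 6 against 5 mice and 5794 (2882 higher, 2912 lower) changed genes and transcripts.

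On day 3 after 162 µg of NRCWE-26, the acute phase, cell cycle and matrix genes were higher and epithelial genes lower, while interferon genes were not raised. Here 0 of 20 list shifts held with an estimated correlation. Running the same way in 4 of 4 slides, Saa3 (7.04 ± 1.23), Ccl7 (5.20 ± 0.73), Saa1 (5.15 ± 0.91), Timp1 (5.13 ± 0.67), the cell adhesion gene Chl1 (5.01 ± 0.55) and Cstdc4 (4.86 ± 0.46) rose the most. Clca1, Dbp, Colq (-3.86 ± 0.47) and Gzma fell the most (adjusted p of the 10 genes up to 3.25e-05). Acute phase proteins rose in 17 of 21, with Serpina3m at 4.21 ± 0.44. For acute phase proteins the median was 1.67 (adjusted p = 8.85e-06, but 0.303 with an estimated correlation), and 18 changed when adjusted over the list alone. Cell cycle genes rose in 24 of 26, such as Birc5 (2.44 ± 0.34) and Rrm2 (2.04 ± 0.30). Cell cycle genes had a median of 1.31 and 24 changed when adjusted over the list alone (adjusted p = 5.55e-15, but 0.298 with an estimated correlation). Extracellular matrix and fibrosis genes rose in 22 of 33, including the stromelysin Mmp3 (3.56 ± 0.36) and Thbs1 (3.26 ± 0.43). The extracellular matrix and fibrosis genes had a median of 1.30 (adjusted p = 3.22e-11, but 0.0756 with an estimated correlation, 123 arrays: 0.00538), with 24 changed when adjusted over the list alone. Of the ciliated cell genes 14 of 15 fell, with Dnah5 at -1.49 ± 0.26, and of the alveolar type 2 cell and surfactant genes 8 of 17, with surfactant protein Sftpc at -1.19 ± 0.18. Among ciliated cell genes the median was -0.92 and 14 changed when adjusted over the list alone, with adjusted p = 1.02e-06, but 0.298 with an estimated correlation. For alveolar type 2 cell and surfactant genes the median was -0.52 (adjusted p = 2.75e-04, but 0.303 with an estimated correlation), and 8 changed when adjusted over the list alone. NK cell markers, higher in these vehicle mice than in those of NM-401 (NM-401 minus NRCWE-26 median -0.42), fell in 9 of 10, with Gzma at -3.38 ± 0.37. NK cell markers had a median of -1.15 and 9 changed when adjusted over the list alone (adjusted p = 2.44e-05, but 0.303 with an estimated correlation). Interferon response genes rose in 1 of 22 and fell in 5, among them Gbp3 (-1.61 ± 0.32) and Psmb9 (-1.48 ± 0.22), and the list as a whole was not shifted. The interferon response genes had a median of 0.20 (adjusted p = 0.718, and 0.925 with an estimated correlation), with 6 changed when adjusted over the list alone. The goblet cell product Clca1 fell by 6.68 ± 1.41, against a vehicle group in which it stood higher than in the NM-401 vehicle group (NM-401 minus NRCWE-26 vehicle -5.97 ± 1.46, adjusted p = 0.105, not past the threshold). Circadian clock genes moved as well, with 8 of 17 lower, 4 higher and Dbp at -4.67 ± 0.59 (NM-401 minus NRCWE-26 vehicle median -0.75). Their median was -0.87 and 12 changed when adjusted over the list alone, with adjusted p = 0.0434, but 0.34 with an estimated correlation. In this comparison of 6 with 4 mice, 5655 (2718 higher, 2937 lower) genes and transcripts changed.

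**Figure D2:**
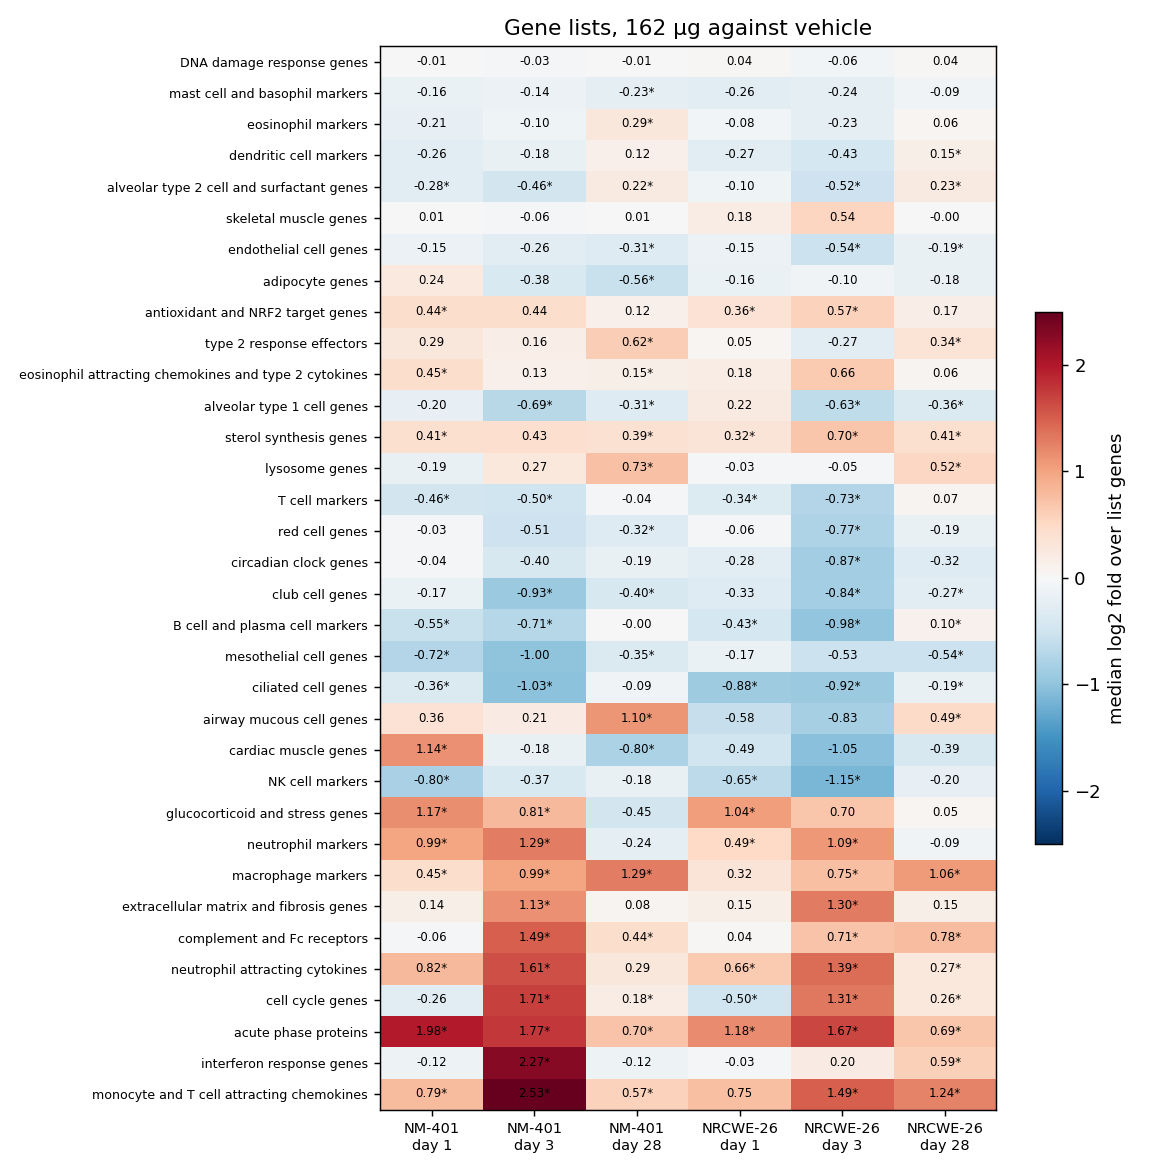
Median log2 fold change of the measured genes of each gene list, 162 µg against vehicle, by material and day. Stars mark an adjusted p under 0.05 with the preset correlation, and 2 list shifts kept it with an estimated correlation, the macrophage markers (0.0303) and lysosome genes (0.0244) after NM-401 on day 28.

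On day 28 after 162 µg of NM-401, genes of macrophages, lysosomes, airway mucous cells and type 2 responses were higher in the lung, and 2 of 20 list shifts held with an estimated correlation. The transmembrane glycoprotein Gpnmb, found in lipid-laden macrophages, rose by 3.77 ± 0.63 (123 arrays: 5.56 ± 0.39), the lipid receptor Trem2 by 2.87 ± 0.49 (123 arrays: 4.22 ± 0.34) and the elastase Mmp12 by 2.78 ± 0.49 (123 arrays: 4.22 ± 0.32), each in 5 of 6 slides. Macrophage markers rose in 14 of 20 genes and in 18 in the 123-array fit. For macrophage markers the median was 1.29 (adjusted p = 3.2e-19, and 0.0303 with an estimated correlation), and 16 changed when adjusted over the list alone. Macrophage markers had a median of 1.92 in the 123-array fit. Lysosome genes rose in 12 of 22, such as the cathepsins Ctsd (1.98 ± 0.32, 123 arrays: 2.88 ± 0.21) and Ctss (1.66 ± 0.34, 123 arrays: 2.53 ± 0.25), and in 17 in the 123-array fit. Lysosome genes had a median of 0.73 and 12 changed when adjusted over the list alone (adjusted p = 8.63e-22, and 0.0244 with an estimated correlation). Airway mucous cell genes rose in 6 of 10 (123 arrays: 10), with Clca1 at 3.64 ± 1.24 (123 arrays: 4.68 ± 1.11) and the anion exchanger Slc26a4 at 2.85 ± 0.70 (123 arrays: 4.10 ± 0.62). The airway mucous cell genes had a median of 1.10 (adjusted p = 2.96e-07, but 0.191 with an estimated correlation), with 9 changed when adjusted over the list alone. In the 123-array fit airway mucous cell genes had a median of 1.75. Type 2 response effectors rose in 7 of 15, including the chitinase-like Chil3 (3.39 ± 0.55, 123 arrays: 4.84 ± 0.46) and the arginase Arg1 (2.94 ± 0.62, 123 arrays: 4.44 ± 0.56). Among type 2 response effectors the median was 0.62 and 7 changed when adjusted over the list alone, with adjusted p = 2.57e-05, but 0.191 with an estimated correlation. Acute phase proteins rose in 6 of 21 (123 arrays: 13), Saa3 by 3.35 ± 1.08 (123 arrays: 4.97 ± 0.98). For acute phase proteins the median was 0.70 (adjusted p = 1.47e-05, but 0.346 with an estimated correlation), and 7 changed when adjusted over the list alone. The rises of Egr1 (1.06 ± 0.37), Nr5a2 (0.64 ± 0.14), Ahr (0.64 ± 0.17, but -0.003 from another probe of the gene) and Stard5 (0.64 ± 0.14) ran the same way in 6 of 6 slides. So did the falls of Dll1 (-0.81 ± 0.20), Rapgef5 (-0.75 ± 0.15), Tcf21 (-0.70 ± 0.20) and Cemip2 (-0.68 ± 0.14). Because slide 9 ran opposite to the others, only 4 rises and 7 falls of 622 changed genes with a symbol met this rule. Genes that follow the response on the other slides mostly fail it, so it does not mark the most consistent genes here. In total 785 (532 higher, 253 lower, range 495 to 2001) genes and transcripts changed (6 mice against 6) and 2001 in the 123-array fit.

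On day 28 after 162 µg of NRCWE-26, macrophage, chemokine and complement receptor genes were higher, though 0 of 19 list shifts held with an estimated correlation. Saa3 rose by 4.16 ± 1.14 (123 arrays: 6.09 ± 1.05), Gpnmb by 3.26 ± 0.66 (123 arrays: 4.83 ± 0.42), Cxcl5 by 2.98 ± 0.80 (123 arrays: 4.67 ± 0.76) and Jchain, the joining chain of secreted antibodies, by 2.64 ± 0.44 (123 arrays: 3.66 ± 0.36), each in 4 of 5 slides. Macrophage markers rose in 11 of 20, with a median of 1.06 (adjusted p = 1.03e-15, but 0.0958 with an estimated correlation). When adjusted over the list alone, 15 changed. In the 123-array fit they rose in 17, with a median of 1.66 and adjusted p = 8.15e-04 with an estimated correlation. Monocyte and T cell attracting chemokines rose in 8 of 16, such as Ccl8 (2.33 ± 0.57, 123 arrays: 3.42 ± 0.54) and Ccl7 (2.23 ± 0.68, 123 arrays: 3.01 ± 0.65). The monocyte and T cell attracting chemokines had a median of 1.24 (adjusted p = 1.23e-07, but 0.112 with an estimated correlation), with 10 changed when adjusted over the list alone. Complement and Fc receptors rose in 7 of 17 and in 14 in the 123-array fit, with C1qb at 1.25 ± 0.31 (123 arrays: 1.87 ± 0.28). Among complement and Fc receptors the median was 0.78 and 11 changed when adjusted over the list alone, with adjusted p = 2.53e-11, but 0.0958 with an estimated correlation (123 arrays: 0.0491). Lysosome genes rose in 8 of 22 (123 arrays: 15), Ctss by 1.79 ± 0.36 (123 arrays: 2.65 ± 0.27). For lysosome genes the median was 0.52 (adjusted p = 1.47e-12, but 0.0958 with an estimated correlation, 123 arrays: 0.00156), and 9 changed when adjusted over the list alone. B cell and plasma cell markers rose in 3 of 16 (123 arrays: 6), Tnfrsf17 by 1.17 ± 0.17. B cell and plasma cell markers had a median of 0.10 and 5 changed when adjusted over the list alone (adjusted p = 0.0014, but 0.386 with an estimated correlation). The T cell costimulator Icos (1.05 ± 0.23), Rab5c (0.92 ± 0.17), Oosp1 (0.79 ± 0.18), Cd164l2 (0.66 ± 0.14) and the adenosine receptor Adora2a (0.62 ± 0.16) rose in 5 of 5 slides, and Lrrn4 (-0.94 ± 0.24), Camk2b (-0.88 ± 0.26), Chst4 (-0.80 ± 0.25) and Epha1 (-0.75 ± 0.18) fell in 5 of 5. Of all genes and transcripts, 520 (448 higher, 72 lower, range 2 to 1823) changed (6 mice against 5), and 1823 in the 123-array fit, but 2 with each day fitted alone and 179 to 1243 with 1 array left out (without 162 µg replicate 3 and replicate 1).

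**Figure D3:**
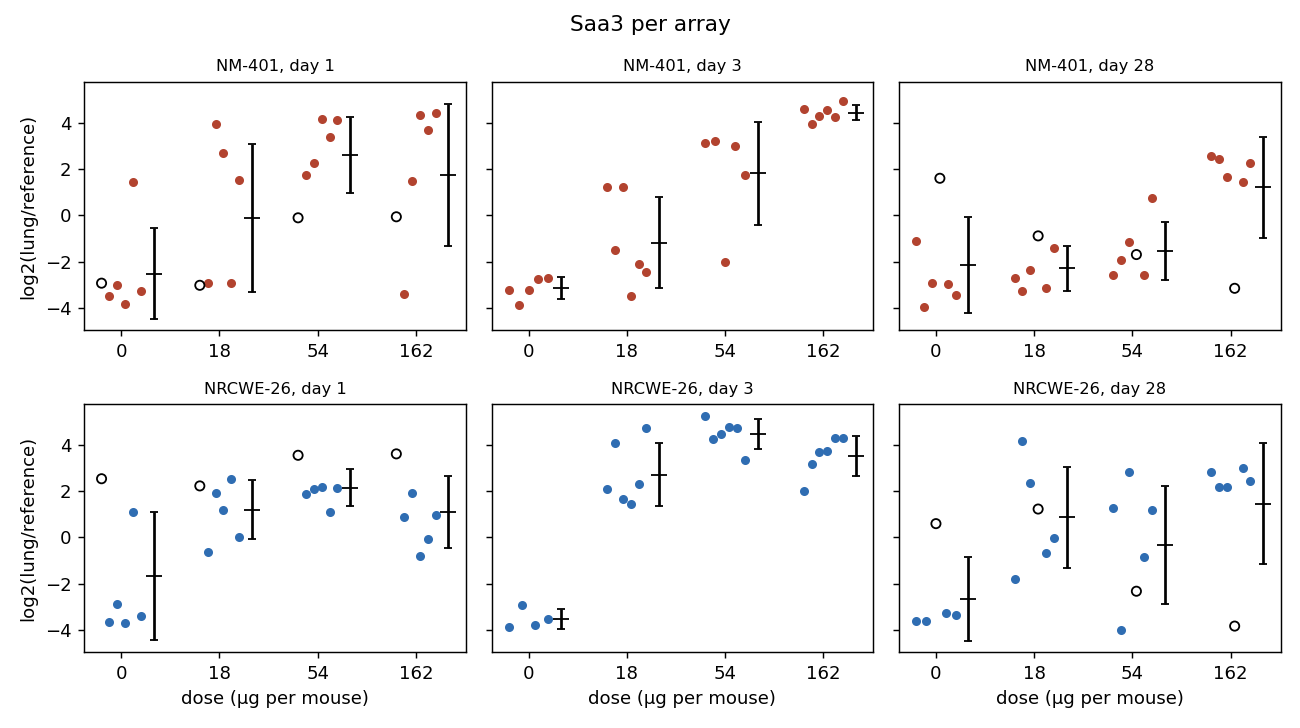
Log2 ratio of lung to reference for Saa3 on each array by dose (µg), material and day, with mean ± SD, and open circles for slides 1 and 9. After 162 µg the log2 fold of Saa3 was 4.29, 7.66 and 3.35 for NM-401 on days 1, 3 and 28, and 2.74, 7.04 and 4.16 for NRCWE-26.

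At 18 and 54 µg of NM-401, the eosinophil chemokine Ccl24 was higher on days 1 and 3. On day 1 after 18 µg, Slc26a4 rose by 2.86 ± 0.70, Ccl24 by 2.62 ± 0.69 and the related chemokine Ccl11 by 2.37 ± 0.48, while Rnu1b6 (-1.38 ± 0.25) and Galnt15 (-0.94 ± 0.21) fell, among 132 (93 higher, 39 lower, range 60 to 430) changed genes and transcripts (123 arrays: 430). After 54 µg, Saa3 rose by 5.11 ± 1.08, Clca1 by 4.57 ± 1.24 (123 arrays: 5.37 ± 1.11) and Ccl24 by 4.37 ± 0.69, while Fabp1 (-1.74 ± 0.52) fell, among 721 (494 higher, 227 lower, range 624 to 1399) changed (123 arrays: 1182). On day 3 after 18 µg, Clca1 rose by 6.97 ± 1.33, Slc26a4 by 3.71 ± 0.75 and Ccl24 by 3.598 ± 0.73, while Anp32a (-1.72 ± 0.49) fell, and 693 (458 higher, 235 lower, range 495 to 1373) changed. Airway mucous cell genes rose there in 7 of 10 (median 1.93, adjusted p = 3.62e-10, and 0.0341 with an estimated correlation). Type 2 response effectors rose in 10 of 15 (median 0.80, adjusted p = 1.01e-09, and 0.0206 with an estimated correlation). Eosinophil markers rose in 4 of 8 (median 0.74, adjusted p = 4e-06, and 0.0206 with an estimated correlation). Cell cycle genes rose in 17 of 26 (median 0.76, adjusted p = 1.73e-23, and 0.0341 with an estimated correlation). Adjusted over each list alone, 8, 11, 5 and 18 changed. The NM-401 vehicle mice already stood lower than those of NRCWE-26 (medians -1.035, -0.285, -0.086 and -0.24, the eosinophil one not past the threshold). After 54 µg on day 3, Clca1 rose by 5.82 ± 1.38, Saa3 by 5.03 ± 1.21 and Ccl24 by 4.48 ± 0.76, while Fabp1 (-1.89 ± 0.57) fell, and 1673 (1054 higher, 619 lower, range 1202 to 2612) changed. On day 28 fewer genes passed: 65 (12 higher, 53 lower, range 23 to 350) after 18 µg and 79 (22 higher, 57 lower, range 29 to 401) after 54 µg, or 155 and 401 in the 123-array fit. Vapb (1.49 ± 0.28), Rnf144a (1.001 ± 0.23) and Ahr (0.95 ± 0.17) rose and the neutrophil genes S100a8 (-1.52 ± 0.42) and Cxcr2 (-1.28 ± 0.29) fell after 18 µg, against a vehicle group in which replicate 5 had neutrophil markers at a mean of 3.032 (1.772 ± 0.222, SD, in the other arrays). After 54 µg, Chil3 (1.97 ± 0.55, 123 arrays: 2.67 ± 0.46), Vapb (1.46 ± 0.28) and Tatdn2 (0.96 ± 0.25) rose, and Zbtb16 (-1.77 ± 0.42) and Per1 (-1.49 ± 0.42) fell.

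At 18 and 54 µg of NRCWE-26, interferon genes were higher on days 3 and 28, and the clock output gene Dbp was lower on every day. The vehicle groups differed in clock genes too (NM-401 minus NRCWE-26 median -0.64 on day 1 and -0.75 on day 3). Interferon response genes rose on day 3 in 21 of 22 after 18 µg and in 22 of 22 after 54 µg. The interferon response genes at 18 µg had a median of 1.98 (adjusted p = 5.78e-37, and 0.0125 with an estimated correlation), with 21 changed when adjusted over the list alone. Among interferon response genes at 54 µg the median was 2.54 and 22 changed when adjusted over the list alone, with adjusted p = 3.59e-37, and 0.0159 with an estimated correlation. On day 28 they rose in 11 of 22 after 18 µg and in 12 of 22 after 54 µg. At 18 µg their median was 0.84 (adjusted p = 5.22e-19, but 0.122 with an estimated correlation). At 54 µg it was 0.85 (adjusted p = 4.89e-20, but 0.102 with an estimated correlation). Adjusted over the list alone, 17 and 18 changed. Circadian clock genes fell after 18 µg in 9 of 17 on day 1 and in 10 of 17 on day 3, and 2 rose on either day. On day 1 their median was -0.78 (adjusted p = 1.07e-05, but 0.0705 with an estimated correlation, 123 arrays: 0.0313). On day 3 it was -1.49 (adjusted p = 1.93e-08, and 0.0109 with an estimated correlation). On either day 12 changed when adjusted over the list alone. On day 1 after 18 µg, Slc26a4 rose by 2.81 ± 0.70, Cxcl5 by 2.29 ± 0.75 and the clock activator Arntl by 2.01 ± 0.33, while Dbp (-2.40 ± 0.52) and Per1 (-1.81 ± 0.42) fell, among 305 (166 higher, 139 lower, range 189 to 714) changed genes and transcripts (123 arrays: 714). After 54 µg, Saa3 rose by 3.81 ± 1.08, Cxcl5 by 2.80 ± 0.75 and Saa1 by 2.80 ± 0.81, while Dbp (-2.67 ± 0.52, 123 arrays: -3.50 ± 0.47) and the potassium channel Kcna6 (-1.75 ± 0.22) fell, among 899 (431 higher, 468 lower, range 800 to 1518) changed (123 arrays: 1497). On day 3 after 18 µg, Saa3 rose by 6.24 ± 1.23 and Cxcl10 by 4.56 ± 0.77, Cxcl5 was at least 17.9-fold higher, and Dbp (-4.01 ± 0.59) and Zbtb16 (-2.48 ± 0.48) fell, among 1122 (802 higher, 320 lower). After 54 µg on day 3, Saa3 (7.99 ± 1.23), Cxcl10 (6.12 ± 0.77) and Saa1 (5.94 ± 0.91) rose, and Clca1 (-5.24 ± 1.41) and Dbp (-3.39 ± 0.59) fell, among 2252 (1384 higher, 868 lower). Cardiac muscle genes fell in the same comparison in 10 of 13 (NM-401 minus NRCWE-26 vehicle mice: median -0.83). For cardiac muscle genes the median was -2.15 (adjusted p = 1.27e-05, but 0.35 with an estimated correlation), and 12 changed when adjusted over the list alone. On day 28 after 18 µg, Cxcl5 (4.12 ± 0.80, 123 arrays: 4.98 ± 0.76), Ly6i (3.095 ± 0.57, 123 arrays: 3.79 ± 0.52) and Ly6f (2.83 ± 0.52, 123 arrays: 3.44 ± 0.46) rose and Dbp (-2.87 ± 0.55, 123 arrays: -3.56 ± 0.50) and Nr1d2 (-1.51 ± 0.26) fell. After 54 µg, Ifi27l2a (2.38 ± 0.46), Ly6i (2.21 ± 0.57, 123 arrays: 3.16 ± 0.52) and Irf7 (2.09 ± 0.48) rose and Dbp (-2.70 ± 0.55, 123 arrays: -3.38 ± 0.50) and Tef (-1.501 ± 0.31) fell. These day 28 comparisons held 339 (285 higher, 54 lower, range 7 to 1036) and 300 (247 higher, 53 lower, range 33 to 1037) changed genes and transcripts, or 1036 and 1037 in the 123-array fit.

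Between 162 and 18 µg of the same material, Mt2 stood higher at the larger dose on day 1, and on day 3 interferon genes stood higher at the larger dose of NM-401 and lower at the larger dose of NRCWE-26. For NM-401 on day 1, Mt2 (2.71 ± 0.54, 123 arrays: 3.32 ± 0.39) and Cxcl5 (2.56 ± 0.80) were higher and Spon2 (-2.14 ± 0.40) and Gzma (-1.96 ± 0.34) lower, among 930 (501 higher, 429 lower, range 881 to 1601) changed genes and transcripts (123 arrays: 1601). Glucocorticoid and stress genes were higher in 11 of 14. Glucocorticoid and stress genes had a median of 1.504 and 12 changed when adjusted over the list alone (adjusted p = 2.06e-14, and 0.00526 with an estimated correlation). For NM-401 on day 3, Cxcl10 (5.96 ± 0.68) and Saa3 (5.68 ± 1.09) were higher, Clca1 was at least 598-fold lower and Colq was lower (-3.51 ± 0.42), among 3520 (1694 higher, 1826 lower, range 3460 to 5854). Interferon response genes were higher in 19 of 22. The interferon response genes had a median of 1.81 (adjusted p = 9.06e-15, but 0.165 with an estimated correlation), with 19 changed when adjusted over the list alone. Eosinophil markers were lower in 6 of 8 at the larger dose. Among eosinophil markers the median was -0.96 and 7 changed when adjusted over the list alone, with adjusted p = 3.05e-04, but 0.165 with an estimated correlation. For NM-401 on day 28, Saa3 (3.50 ± 1.08, 123 arrays: 4.65 ± 0.98) and Gpnmb (3.46 ± 0.63, 123 arrays: 4.77 ± 0.39) were higher and Colq (-1.27 ± 0.41) lower, among 558 (451 higher, 107 lower, range 302 to 1177) (123 arrays: 1177), with lysosome genes higher in 12 of 22. For lysosome genes the median was 0.72 (adjusted p = 3.52e-25, and 0.00993 with an estimated correlation), and 12 changed when adjusted over the list alone. For NRCWE-26 on day 1, Mt2 (2.79 ± 0.51) and Akr1c14 (2.59 ± 0.28) were higher and Clca1 (-3.66 ± 1.24, 123 arrays: -4.35 ± 1.11) and Ccl24 (-2.24 ± 0.69) lower, among 1322 (599 higher, 723 lower). On day 3 the activin antagonist Fst (4.84 ± 0.36) and Cstdc4 (4.44 ± 0.40) were higher and the interferon inducible Ifi27l2a (-3.96 ± 0.44) and Ifi44 (-3.93 ± 0.37) lower, among 3881 (1685 higher, 2196 lower, range 3823 to 5942). All 22 measured interferon response genes were lower at 162 than at 18 µg of NRCWE-26 on day 3, and the list mean was lower in 6 of 6 slides. Interferon response genes had a median of -2.10 and 22 changed when adjusted over the list alone (adjusted p = 1.68e-15, but 0.225 with an estimated correlation). On day 28 only 7 (7 higher, 0 lower, range 0 to 237) passed for NRCWE-26 and 237 in the 123-array fit, led by Bcan (1.41 ± 0.24) and Kng2 (0.92 ± 0.20).

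**Figure D4:**
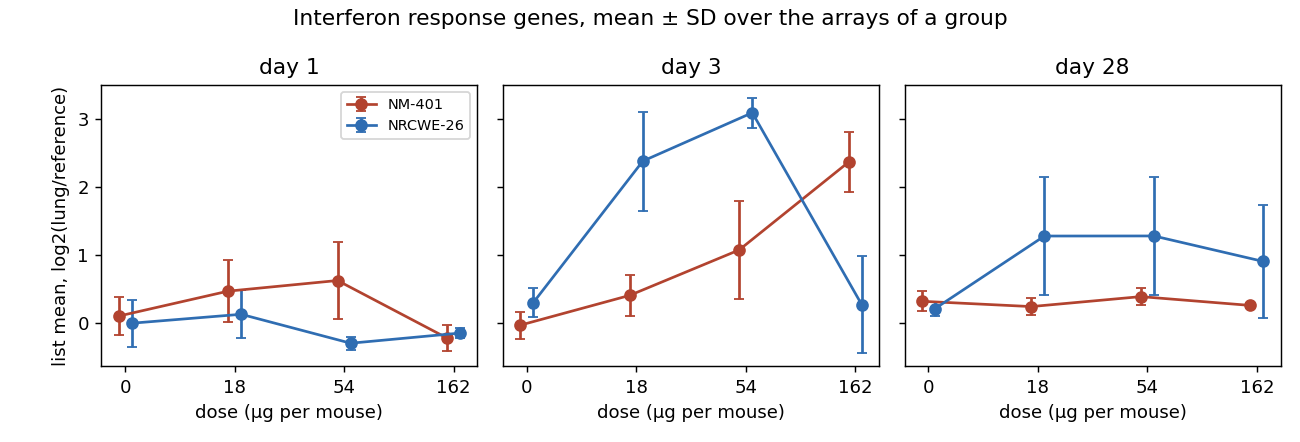
Mean log2 ratio of lung to reference over the 22 measured interferon response genes on each array by dose (µg), material and day, with mean ± SD. On day 3 the list rose in 21 and 22 genes after 18 and 54 µg of NRCWE-26 and in 1 after 162 µg, and in 20 after 162 µg of NM-401.

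The difference between the responses to the long and the short nanotube was tested directly as the response to NM-401 minus the response to NRCWE-26 at the same dose and day, so it includes the difference between the vehicle groups. At 162 µg on day 3 all 22 measured interferon response genes stood higher in the response to NM-401. The interferon response genes had a median of 2.51 (adjusted p = 1.19e-63, and 4.51e-04 with an estimated correlation), with 22 changed when adjusted over the list alone. Cxcl10 (3.81 ± 1.04), Rsad2 (3.43 ± 0.64) and Gbp3 (3.35 ± 0.43) led, and Arntl (-2.16 ± 0.51), Spon2 (-2.03 ± 0.58) and Gdpd2 (-1.71 ± 0.40) were lower, among 336 (303 higher, 33 lower) that differed. These 3 already stood higher in the NM-401 than in the NRCWE-26 vehicle group of day 3, Arntl by 1.84 ± 0.39, Spon2 by 1.92 ± 0.44 (adjusted p = 0.0751) and Gdpd2 by 1.14 ± 0.30 (adjusted p = 0.227). At the lower doses of day 3 the interferon difference ran the other way, lower for NM-401 in 14 of 22 at 18 µg and in 12 of 22 at 54 µg. Among interferon response genes at 18 µg the median was -1.73 and 18 changed when adjusted over the list alone, with adjusted p = 8.74e-27, but 0.051 with an estimated correlation (123 arrays: 0.0497). For interferon response genes at 54 µg the median was -1.71 (adjusted p = 4.1e-21, but 0.113 with an estimated correlation), and 18 changed when adjusted over the list alone. Airway mucous cell genes stood higher for NM-401 in 3 of 10 (123 arrays: 5) at 18 µg and in 5 of 10 at 54 µg on day 3, beside a median of -1.03 between the vehicle groups. Airway mucous cell genes at 18 µg had a median of 1.92 and 7 changed when adjusted over the list alone (adjusted p = 7.15e-10, but 0.0535 with an estimated correlation). In the 123-array fit airway mucous cell genes at 18 µg had adjusted p = 0.031 with an estimated correlation. The airway mucous cell genes at 54 µg had a median of 1.88 (adjusted p = 1.13e-07, but 0.124 with an estimated correlation), with 6 changed when adjusted over the list alone. In the day 3 comparisons 166 (65 higher, 101 lower, range 72 to 365) differed at 18 µg and 413 (130 higher, 283 lower, range 249 to 709) at 54 µg, and 264 at 18 µg in the 123-array fit. On day 1 at 162 µg the secreted airway proteins Bpifb1 (2.73 ± 0.62) and Scgb3a1 (1.86 ± 0.47) and Aoc1 (1.59 ± 0.39) were higher, and Htra1 (-0.92 ± 0.21), Tmem140 (-0.88 ± 0.22) and Thbs3 (-0.87 ± 0.21) lower, among 85 (67 higher, 18 lower, range 8 to 212) (123 arrays: 212). Ciliated cell genes stood higher for NM-401 in 3 of 15, beside a median of -0.31 between the vehicle groups of day 1. Among ciliated cell genes the median was 0.61 and 8 changed when adjusted over the list alone, with adjusted p = 7.34e-13, but 0.193 with an estimated correlation. At 54 µg on day 1 399 (202 higher, 197 lower, range 119 to 636) differed (123 arrays: 636), and at 18 µg limma called 0, with 842 at an unadjusted p under 0.05 and 12 called in the 123-array fit. On day 28, Duox1 (0.74 ± 0.17) was higher and Dnaja1 (-0.91 ± 0.20) and Dusp16 (-0.88 ± 0.19) lower at 162 µg, among 12 (1 higher, 11 lower, range 0 to 167). The day 28 counts were 59 (11 higher, 48 lower, range 0 to 276) at 18 µg and 12 (7 higher, 5 lower, range 0 to 97) at 54 µg, and 276, 97 and 167 at 18, 54 and 162 µg in the 123-array fit.

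The response to 162 µg was compared between day 28 and day 1. For NM-401 the macrophage genes Gpnmb (3.33 ± 0.91, 123 arrays: 4.89 ± 0.57) and Chil3 (3.03 ± 0.79, 123 arrays: 4.70 ± 0.67) stood higher in the day 28 response, and the neutrophil genes Stfa2l1 (-3.76 ± 0.57, 123 arrays: -4.63 ± 0.45) and S100a8 (-3.72 ± 0.61, 123 arrays: -4.53 ± 0.52) lower. Lysosome genes were higher in 12 of 22, neutrophil markers lower in 11 of 18 (against day 28 NM-401 vehicle mice a median of 0.53 above those of NRCWE-26, adjusted p = 2.22e-06) and glucocorticoid and stress genes lower in 10 of 14. For lysosome genes the median was 0.81 (adjusted p = 1.93e-15, and 0.0466 with an estimated correlation), and 12 changed when adjusted over the list alone. Neutrophil markers had a median of -1.12 and 11 changed when adjusted over the list alone (adjusted p = 1.29e-09, and 0.0434 with an estimated correlation). The glucocorticoid and stress genes had a median of -1.68 (adjusted p = 2.22e-09, and 0.0434 with an estimated correlation), with 11 changed when adjusted over the list alone. Cardiac muscle genes were lower in 8 of 13 (NM-401 minus NRCWE-26 vehicle mice of day 1: median -1.78). Among cardiac muscle genes the median was -2.09 and 10 changed when adjusted over the list alone, with adjusted p = 2.52e-06, but 0.415 with an estimated correlation. For NRCWE-26, Clca1 (5.61 ± 1.81, 123 arrays: 8.40 ± 1.62) and Jchain (3.17 ± 0.60, 123 arrays: 4.36 ± 0.49) stood higher and Akr1c14 (-2.92 ± 0.40) and Mt2 (-2.67 ± 0.74) lower. Cell cycle genes were higher in 15 of 26 and ciliated cell genes in 9 of 15. For cell cycle genes the median was 0.73 (adjusted p = 4.69e-07, but 0.592 with an estimated correlation), and 18 changed when adjusted over the list alone. Ciliated cell genes had a median of 0.68 and 9 changed when adjusted over the list alone (adjusted p = 1.98e-08, but 0.523 with an estimated correlation). The responses differed between these days for 1500 (711 higher, 789 lower, range 1338 to 2819) genes and transcripts with NM-401 and 2052 (1120 higher, 932 lower) with NRCWE-26, or 2819 with NM-401 in the 123-array fit.

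The vehicle groups of NM-401 and NRCWE-26 received the same vehicle, and 15, 12 and 5 of the 34 lists were shifted between them on days 1, 3 and 28. With an estimated correlation 0 of these shifts held, but 3 did in the 123-array fit, cardiac muscle genes (adjusted p = 0.0277) and circadian clock genes (0.037) on day 1 and clock genes on day 3 (0.0405). Given as the median of NM-401 minus NRCWE-26 with adjusted p, the lists lower on day 1 were cardiac muscle genes (-1.78, 2.93e-18), ciliated cell genes (-0.31, 3.82e-07), adipocyte genes (-0.78, 4.8e-05), circadian clock genes (-0.64, 5.79e-05), airway mucous cell genes (-0.57, 2.41e-04), glucocorticoid and stress genes (-0.55, 2.41e-04, 123 arrays: 0.0786), cell cycle genes (-0.23, 3.66e-04, 123 arrays: 0.293) and acute phase proteins (-0.37, 0.045, 123 arrays: 0.86), and those higher T cell markers (0.23, 1.48e-04, 123 arrays: 0.271), alveolar type 2 cell and surfactant genes (0.14, 0.0025), alveolar type 1 cell genes (0.11, 0.0127), mesothelial cell genes (0.29, 0.0277), B cell and plasma cell markers (0.15, 0.037, 123 arrays: 0.86), NK cell markers (0.18, 0.039, 123 arrays: 0.999) and red cell genes (0.21, 0.039, 123 arrays: 0.109). On day 3 the lower ones were NK cell markers (-0.42, 1.39e-08), airway mucous cell genes (-1.03, 5.42e-08), cardiac muscle genes (-0.83, 4.94e-06), cell cycle genes (-0.24, 2.22e-05), circadian clock genes (-0.75, 4.96e-05), interferon response genes (-0.30, 1.54e-04), dendritic cell markers (-0.22, 0.00128), type 2 response effectors (-0.28, 0.00359), endothelial cell genes (-0.12, 0.0167) and glucocorticoid and stress genes (-0.33, 0.0219), and the higher ones sterol synthesis genes (0.16, 0.00207) and mesothelial cell genes (0.23, 0.00463). On day 28 ciliated cell genes (-0.24, 2.8e-05) were lower and neutrophil markers (0.53, 2.22e-06), cell cycle genes (0.19, 0.00258), glucocorticoid and stress genes (0.28, 0.0115) and complement and Fc receptors (0.26, 0.0146) higher. On day 1 the NM-401 vehicle group had more Arntl (1.77 ± 0.33) and Spon2 (1.72 ± 0.38) and less of the cardiac genes Sln (-3.02 ± 0.69) and Myh6 (-2.96 ± 0.59, 123 arrays: -3.70 ± 0.64), among 78 (16 higher, 62 lower, range 21 to 197) (123 arrays: 197). On day 3, 5 genes and transcripts differed, among them Arntl (1.84 ± 0.39), the clock gene Per3 (-1.004 ± 0.21) and the cyclin Ccna1 (-0.86 ± 0.17), while 18 differed in the 123-array fit (0 to 19 over all alternatives). On day 28 the heat shock genes Hsph1 (1.19 ± 0.18) and Hspa1a (1.01 ± 0.21) were higher and Ccn1 (-1.22 ± 0.28) and Rsph14 (-1.03 ± 0.22) lower, among 75 (21 higher, 54 lower, range 10 to 200) (123 arrays: 181). The arrays of the NRCWE-26 vehicle groups lay in row 1 of their slides and those of the NM-401 vehicle groups in row 2, so row and material cannot be separated in these comparisons.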

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

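The tests of explanations for slides 1 and 9, the clock genes and the interferon genes were chosen after the results they bear on had been seen. An array was singled out when its list mean lay far from the rest of its group by Dixon's criterion, and 19 of 120 tests (5 lists in each of 24 groups) found such an array, where 5% would by chance. A difference between materials or days was singled out when its own test in limma passed.

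The arrays of slide 9 run against their labels, pairs of arrays on slide 1 are nearly alike, and most of the outlying arrays lie on these 2 slides. On slide 9 the response to 162 µg had r = -0.81 for NM-401 and r = -0.74 (-0.743) for NRCWE-26 with the other day 28 slides, which singled the slide out. Weak signal is argued against by 50.98% of probes above background, inside the range of 44 to 57.53% of the other day 28 slides, while a reversed order of the dose labels cannot be told apart from other causes, since the difference of the 54 and 18 µg arrays (r = -0.132 and -0.293) is as variable on the other day 28 slides (r from -0.293 to 0.355). On slide 1 the pairs labelled NM-401 54 and 162 µg, NRCWE-26 54 and 162 µg, and NM-401 vehicle and 18 µg differed by a median of at most 0.0705 (log2), less than any of 442 pairs on other slides (closest 0.0889). That is what 1 RNA on both arrays would give, but these pairs were picked for closeness. It fails for a further neighbouring pair, NRCWE-26 vehicle and 18 µg (0.168), and so for the pairs as a set. The order of hybridisation and differences between mice stay open, since the labels give nothing that tests them.

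A clock score of 8 evening genes minus 3 morning genes was lower after NRCWE-26 than in its vehicle mice at every dose, from -3.321 ± 0.466 at 18 µg on day 3 to -0.938 ± 0.433 at 162 µg on day 28. At 18 µg it differed by -1.751 or further from 0 on each of the 3 days. Between 162 and 18 µg it differed by at most 0.883 ± 0.411, opposite to a response growing with dose. Vehicle groups of the same vehicle differed too, NM-401 minus NRCWE-26 by -1.754 ± 0.411 and -2.098 ± 0.481 on days 1 and 3, while the difference on day 28 (-0.637 ± 0.433) was within 2 standard errors. A candidate explanation is that the NRCWE-26 vehicle mice were killed at another time of day, but the labels give no times. The vehicle differences of days 1 and 3 argue against a dose-independent effect of NRCWE-26 as the only cause. Scores on these days averaged 2.469 and 2.768 in NRCWE-26 vehicle mice and at most 0.996 and 1.324 in other groups. On day 28 such an effect stays open.

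Interferon genes were lower at 162 than at 18 µg of NRCWE-26 on day 3. Swapped labels are argued against by Mt2, which stood higher at 162 µg by 4.03 (4.032), as after 162 µg on day 1. A few arrays are argued against by the list mean, which was lower in 6 of 6 slides, by -3.365 to -0.566. A response to this material that differs with dose in kind remains a hypothesis, found and tested on the same data.

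Other outlying arrays, given as the mean log2 ratio of a list, follow. For acute phase proteins these were, on slide 9 (day 28), the arrays labelled NM-401 162 µg (0.424) and 18 µg (1.203). Others there were NRCWE-26 162 µg (0.475) and vehicle (1.239, short of 1.938 in the other 162 µg arrays). For neutrophil markers they were NM-401 18 µg day 28 replicate 4 (1.182), NM-401 54 µg day 28 replicate 4 (1.437), NM-401 vehicle day 28 replicate 5 (3.032), and on slide 1 NRCWE-26 18 µg (2.617) and vehicle (2.574) of day 1. For macrophage markers they were, on slide 9, NM-401 162 µg (0.635) and vehicle (2.678) and NRCWE-26 162 µg (0.592) and vehicle (2.03) of day 28, and otherwise NM-401 54 µg day 28 replicate 5 (0.633), NM-401 54 µg day 3 replicate 5 (0.595) and, on slide 1, NRCWE-26 54 µg day 1 (1.323). For interferon response genes they were NM-401 18 µg day 1 replicate 2 (1.363), NM-401 54 µg day 1 replicate 4 (1.688) and NRCWE-26 162 µg day 1 replicate 2 (-0.001).

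The responses to the materials differed in 399 genes and transcripts at 54 µg and 85 at 162 µg on day 1, in 166, 413 and 336 at 18, 54 and 162 µg on day 3, and in 59, 12 and 12 on day 28. The response to 162 µg differed between day 28 and day 1 in 1500 for NM-401 and 2052 for NRCWE-26. Genes with the largest differences between materials at 162 µg were Bpifb1 (2.732), Scgb3a1 (1.865), Aoc1 (1.59), Htra1 (-0.921), Tmem140 (-0.88) and Thbs3 (-0.87) on day 1. On day 3 they were Cxcl10 (3.808), Rsad2 (3.427), Gbp3 (3.354), Arntl (-2.159), Spon2 (-2.027) and Gdpd2 (-1.709), and on day 28 Duox1 (0.742), Dnaja1 (-0.913) and Dusp16 (-0.88). Between days they were Gpnmb (3.325), Chil3 (3.033), Stfa2l1 (-3.758) and S100a8 (-3.722) for NM-401, and Clca1 (5.608), Jchain (3.165), Akr1c14 (-2.915) and Mt2 (-2.673) for NRCWE-26.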

How the results depend on the processing

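The fit without slides 1 and 9 and the list tests with an estimated correlation were chosen after the results were seen, and the other alternatives were planned. No count of changed genes moved beyond 1.5 times without background correction, with the authors' table, with quantile normalization (which leaves every log ratio as it is by construction) or with 1 value per probe. Signal over background limits which genes can be read: 508 of the 560 list genes were measured, the others having no matched probe well above background. The cause of each change below was not tested, except where fewer arrays or fewer genes enter by construction. No paired analysis was possible because replicate numbers in the labels do not link animals across groups, and slides served as blocks.

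Without slides 1 and 9, the changed genes and transcripts for 18, 54 and 162 µg were 430, 1182 and 2497 for NM-401 on day 1, 155, 401 and 2001 on day 28, and for NRCWE-26 714, 1497 and 2992 on day 1 and 1036, 1037 and 1823 on day 28. For 162 against 18 µg they were 1601 and 1177 for NM-401 on days 1 and 28 and 237 for NRCWE-26 on day 28. Differences between materials at 18, 54 and 162 µg were 12, 636 and 212 on day 1 and 276, 97 and 167 on day 28, and 264 at 18 µg on day 3. Day 28 minus day 1 gave 2819 for NM-401, and the vehicle groups differed in 197, 18 and 181 on days 1, 3 and 28.

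With the processed intensities, NM-401 at 18, 54 and 162 µg gave 319, 1399 and 2681 on day 1 and 350, 260 and 1390 on day 28, and at 18 and 54 µg on day 3 1373 and 2612. NRCWE-26 gave 542, 1518 and 3515 on day 1. For 162 against 18 µg they gave 5854 and 1030 for NM-401 on days 3 and 28 and 5942 for NRCWE-26 on day 3. The materials differed in 31 at 162 µg on day 1 and 7 on day 28, and the vehicle groups in 125 on day 1 and 0 on day 3 (limma in each case). They also put 1600029I14Rik at 0.002 for NRCWE-26 162 µg on day 1 and Erg at 0.284 for NRCWE-26 162 µg on day 3. The share of changed genes that were higher moved from 82.3% to 68.9% for NRCWE-26 54 µg on day 28, and for the difference between materials at 54 µg from 58.3% to 75% on day 28 and from 31.5% to 41.7% on day 3. Without background correction that share moved from 40% to 28.6% for the vehicle groups of day 3.

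With each day fitted alone, day 28 gave 37, 29 and 495 for NM-401 and 7, 33 and 2 for NRCWE-26 at 18, 54 and 162 µg, and 302 and 0 for 162 against 18 µg. The materials differed in 27 at 162 µg on day 1, and on day 28 in 0 at 162 µg and 0 at 18 µg, and the vehicle groups in 21 and 12 on days 1 and 3. Without a slide block, NM-401 18 µg gave 60 on day 1 and 23 on day 28, NM-401 54 µg on day 28 31, NRCWE-26 18 µg on day 1 189, NRCWE-26 54 µg on day 28 198, and NRCWE-26 162 against 18 µg on day 28 2. The materials then differed in 119 and 8 at 54 and 162 µg on day 1, 85 and 249 at 18 and 54 µg on day 3 and 4, 0 and 2 at 18, 54 and 162 µg on day 28, and the vehicle groups in 33, 0 and 10. With the vehicle groups pooled, NM-401 18 µg on day 1 gave 248, and the materials differed in 13 at 162 µg on day 1, 365 and 709 at 18 and 54 µg on day 3, and 212 and 88 at 18 and 162 µg on day 28. The difference on day 28 was 2 at 162 µg and 26 at 18 µg with no filter, 0 at 162 µg with the stricter filter and 22 at 54 µg with slide as a random block. Other probes put Ahr at -0.003 for NM-401 162 µg on day 28 and Erg at 0.001 for NM-401 162 µg on day 3.

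With an estimated correlation the number of lists shifted at 162 µg went from 16, 16 and 20 to 0, 0 and 2 for NM-401 on days 1, 3 and 28, and from 11, 20 and 19 to 0, 0 and 0 for NRCWE-26. Of 560 values of named genes, the processed intensities left 520, no slide block 529, each day alone 468 and pooled vehicle groups 517 on their side of the threshold in the same direction. Other probes, where a gene has them, left 61 of 115, with 52 short of the threshold and 2 reversed. With the preset correlation, of the list tests at 162 µg that passed before or under the alternative, 93 of 116 kept direction and side with pooled vehicle groups, 92 of 104 with the processed intensities and 102 of 102 with quantile normalization.

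Leaving out 1 array at a time gave 495 to 833, 1202 to 2035 and 5560 to 5964 for NM-401 at 18, 54 and 162 µg on day 3, and 803 to 1209, 1979 to 2422 and 5464 to 6168 for NRCWE-26. On day 28 NRCWE-26 ranged from 161 (without vehicle replicate 4) to 953 (without vehicle replicate 1), from 91 (without 54 µg replicate 2) to 716 (without vehicle replicate 1), and from 179 (without 162 µg replicate 3) to 1243 (without 162 µg replicate 1) at the 3 doses, and 6, 8 and 8 of 11 arrays moved these counts beyond 1.5 times. The difference between materials ranged on day 3 from 72 (without NRCWE-26 vehicle replicate 3) to 201, from 261 (without that array) to 522 and from 241 to 411. On day 28 it ranged from 2 (without NRCWE-26 vehicle replicate 2) to 234 (without vehicle replicate 1), from 0 (without NRCWE-26 54 µg replicate 2) to 48 (without vehicle replicate 1), and from 1 (without NRCWE-26 vehicle replicate 2) to 91 (without NRCWE-26 162 µg replicate 1). Day 28 minus day 1 for NRCWE-26 ranged from 1761 to 2555, and the vehicle groups from 0 (without NM-401 replicate 1) to 19 (without NM-401 replicate 4) on day 3 and from 29 (without NRCWE-26 replicate 5) to 200 (without NRCWE-26 replicate 1) on day 28. Replicate 1 of the day 28 groups lies on slide 9.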

Other observations

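The counts of regrouped arrays in this part were set up after the comparisons had been seen, and the gene lists had been fixed before. At 162 µg further gene groups moved that the report leaves out. Sterol synthesis genes rose on day 3 after NRCWE-26 in 14 of 22, such as Hsd17b7 (1.68 ± 0.20) and Cyp51 (1.57 ± 0.20), and on day 28 after NM-401 in 5 of 22 (123 arrays: 11), such as Mvd (0.77 ± 0.16). The sterol synthesis genes on day 3 had a median of 0.70 (adjusted p = 3.72e-05, but 0.303 with an estimated correlation), with 14 changed when adjusted over the list alone. Among sterol synthesis genes on day 28 the median was 0.39 and 5 changed when adjusted over the list alone, with adjusted p = 9.84e-08, but 0.249 with an estimated correlation. Antioxidant and NRF2 target genes moved both ways on day 3 after NRCWE-26, with 12 higher, such as Mt2 at 4.36 ± 0.57, and 5 lower, such as the glutathione transferase Gsta3 at -2.10 ± 0.33. For antioxidant and NRF2 target genes the median was 0.57 (adjusted p = 0.0117, but 0.303 with an estimated correlation), and 17 changed when adjusted over the list alone. Red cell genes fell in 6 of 6 in the same comparison, with Hba-a1 at -0.91 ± 0.17. Red cell genes had a median of -0.77 and 6 changed when adjusted over the list alone (adjusted p = 0.00934, but 0.303 with an estimated correlation). The DNA damage response list was not shifted by camera after 162 µg of NM-401 or NRCWE-26, with adjusted p = 0.713, 0.965 and 0.901 for NM-401 and 0.218, 0.718 and 0.468 for NRCWE-26 on days 1, 3 and 28, although Cdkn1a rose on day 3 by 2.08 ± 0.27 and 2.08 ± 0.29.

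Each count of changed genes and transcripts was compared with 100 splits of the same arrays into groups of the same sizes, with the real split included and the slide block kept in the fit. For the difference between materials the exposed and the vehicle arrays were each dealt anew between materials, and for the days whole slides were. No allowance was made for the number of these tests, 38 with all arrays. Real counts can differ by 1 or 2 from those above because fitted values replace left-out spots here. For doses against vehicle, few splits gave as many for NM-401 18 µg on day 1 (real 132, highest other 107, 1 of 100 splits), NM-401 54 µg on day 1 (real 721, highest other 728, 2 of 100), NM-401 162 µg on day 1 (real 1568, highest other 2007, 4 of 100), NM-401 18 µg on day 3 (real 693, highest other 396, 1 of 100), NM-401 54 µg on day 3 (real 1674, highest other 1047, 1 of 100) and NM-401 162 µg on day 3 (real 5794, highest other 3405, 1 of 100). Among the NRCWE-26 doses, few splits gave as many for NRCWE-26 54 µg on day 1 (real 899, highest other 1540, 2 of 100), NRCWE-26 162 µg on day 1 (real 2254, highest other 1967, 1 of 100), NRCWE-26 18 µg on day 3 (real 1122, highest other 619, 1 of 100), NRCWE-26 54 µg on day 3 (real 2252, highest other 1413, 1 of 100) and NRCWE-26 162 µg on day 3 (real 5655, highest other 4253, 1 of 100). Few splits also gave as many for NRCWE-26 18 µg on day 28 (real 339, highest other 1007, 3 of 100) and NRCWE-26 162 µg on day 28 (real 520, highest other 1421, 3 of 100). These counts fall to 7 and 2 with each day fitted alone, so chance cannot be excluded for them. Nor can chance be excluded for NM-401 18 µg on day 28 (real 66, highest other 284, 6 of 100), NM-401 54 µg on day 28 (real 79, highest other 319, 6 of 100), NM-401 162 µg on day 28 (real 785, highest other 1095, 8 of 100), NRCWE-26 18 µg on day 1 (real 305, highest other 971, 5 of 100) and NRCWE-26 54 µg on day 28 (real 300, highest other 1126, 8 of 100). For 162 against 18 µg, few splits gave as many for NM-401 on day 1 (real 930, highest other 1271, 4 of 100), NM-401 on day 3 (real 3520, highest other 2281, 1 of 100), NM-401 on day 28 (real 558, highest other 701, 2 of 100), NRCWE-26 on day 1 (real 1322, highest other 667, 1 of 100) and NRCWE-26 on day 3 (real 3881, highest other 2920, 1 of 100). Chance cannot be excluded for NRCWE-26 on day 28 (real 7, highest other 51, 17 of 100). For the vehicle groups of day 3, few splits gave as many (real 5, highest other 17, 3 of 100), but the count falls to 0 without a slide block, so chance cannot be excluded. Nor can it for day 1 (real 78, highest other 164, 5 of 100) and day 28 (real 76, highest other 783, 13 of 100). For the difference between materials, few splits gave as many for 54 µg on day 1 (real 400, highest other 183, 1 of 100), 18 µg on day 3 (real 166, highest other 195, 2 of 100), 54 µg on day 3 (real 414, highest other 750, 3 of 100) and 162 µg on day 3 (real 336, highest other 8, 1 of 100). Chance cannot be excluded for 18 µg on day 1 (real 0, highest other 16, 100 of 100), 162 µg on day 1 (real 85, highest other 664, 5 of 100), 18 µg on day 28 (real 59, highest other 1040, 7 of 100), 54 µg on day 28 (real 12, highest other 916, 13 of 100) and 162 µg on day 28 (real 12, highest other 800, 21 of 100). For the day 28 minus the day 1 response to 162 µg, few splits gave as many for NM-401 162 (real 1500, highest other 1694, 2 of 100) and NRCWE-26 162 (real 2054, highest other 1880, 1 of 100). Without slides 1 and 9 the splits decide nothing about chance, because those slides were left out for going against the real split, and they gave for NM-401 18 µg on day 1 (real 430, highest other 324, 1 of 100), NM-401 54 µg on day 1 (real 1182, highest other 858, 1 of 100), NM-401 162 µg on day 1 (real 2497, highest other 1912, 1 of 100), NM-401 18 µg on day 28 (real 155, highest other 342, 4 of 100), NM-401 54 µg on day 28 (real 401, highest other 287, 1 of 100) and NM-401 162 µg on day 28 (real 2000, highest other 1214, 1 of 100). They gave likewise for NRCWE-26 18 µg on day 1 (real 714, highest other 283, 1 of 100), NRCWE-26 54 µg on day 1 (real 1497, highest other 820, 1 of 100), NRCWE-26 162 µg on day 1 (real 2992, highest other 1625, 1 of 100), NRCWE-26 18 µg on day 28 (real 1036, highest other 1050, 2 of 100), NRCWE-26 54 µg on day 28 (real 1035, highest other 1369, 4 of 100) and NRCWE-26 162 µg on day 28 (real 1822, highest other 1709, 1 of 100). Where another split called several times as many genes as the real one, as for NM-401 18 µg on day 28 (284 against 66), NRCWE-26 162 µg on day 28 (1421 against 520) or the materials at 18 µg on day 28 (1040 against 59), the arrays hold a structure other than the groups, which was not identified.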
